A study of Mus musculus with 14 samples.

How the data were processed

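RNA-seq of mouse (C57BL/6) liver cells was analysed from gene tables. Per the labels, total RNA was prepared with RNeasy kits, libraries with a TruSeq Stranded mRNA kit, and paired-end reads came from an Illumina HiSeq instrument. The 14 libraries fell into 7 groups of 2 named in the labels: FH, FH Yap-/-, BM 1D, BM 3D, BM 3W, BM 3W Yap-/- and LBDXL 3W. Library numbers were taken from the labels and paired no libraries in the main fit.

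The authors deposited a table of raw counts per gene and a table of FPKM for the same libraries. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq were used with the GRCm38.p6 assembly, without versions or settings. Whether counting used the strand of the reads is not given in the sources used here. Values of genes that overlap others on the opposite strand or have close paralogs, such as the Cyp2b, Cyp3a, Cyp2c, Sult and Mup families, are therefore uncertain. Each table held 21878 genes, 4326 of them at 0 counts in all libraries. The symbols of 27 genes had been altered by a spreadsheet and were restored from NCBI gene IDs. Coordinates were taken from NCBI RefSeq for GRCm38.p6. Counts were 0 with FPKM above 0 in 1240 gene and library pairs, and 7 pairs had over 20 counts with FPKM at 0. Mitochondrially encoded genes and Xist were not analysed here, and some single genes are not reported here.

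Depth ran from 15501005 counts in BM 1D 2 to 21220365 in FH Yap-/- 1. TMM factors ran from 0.65 to 1.69, lowest in FH and highest in BM 3W 2. Albumin held 0.482 to 17.3% of the counts of a library and the 20 most abundant genes 7.27 to 32.7%. A gene at 0 counts in a group was placed at 3 counts per library to give a bound on its fold, a floor of 0.141 to 0.194 CPM before TMM scaling.

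Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on group (14100 genes) and scaled by TMM. All 14 libraries were fitted in 1 model with a mean for each group, and contrasts were tested with the quasi-likelihood F-test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 14100 genes were called. The comparisons were BM 1D, BM 3D, BM 3W and LBDXL 3W each with FH, BM 3D with BM 1D, BM 3W with BM 3D, LBDXL 3W with BM 3W, each Yap-/- group with its control, and the interaction of Yap-/- with culture. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are TMM-scaled CPM.

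Gene lists (36 fixed, 35 with at least 3 tested members) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with the correlation estimated from the libraries is given beside it, because it ended nearly every list call. Lists cover hepatocyte functions, YAP targets, cytoskeleton and matrix, stress responses, sex-biased genes and other cell types. Principal components were taken from log2 CPM.

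These tests, lists, comparisons and alternatives were fixed before the data were examined. Genes could be named if they belonged to a fixed panel of 16, were among the 5 largest rises or falls past the threshold with a mean of at least 10 CPM in the higher group and no overlap between libraries, or were among the 4 members with the smallest p of a list that passed. Predicted, Rik, pseudogene and mitochondrial symbols were left out of the largest changes. Cell type and sex lists were eligible whether or not they passed. Eligible genes whose call held under the alternatives were preferred after the values were seen. Of the eligible called genes, 93 of 109 held under every alternative in BM 1D against FH. Against FH too, 99 of 118 held in BM 3D, 116 of 125 in BM 3W and 46 of 93 in LBDXL 3W. From BM 1D to BM 3D 0 of 38 held, and from BM 3D to BM 3W 71 of 113. Against BM 3W, 107 of 125 held in LBDXL 3W and 91 of 117 in BM 3W Yap-/-. In FH Yap-/- against FH 6 of 28 held, and in the interaction 60 of 103. These are upper bounds, as not every alternative was applied to each gene. The text thus shows more stable genes than the eligible set holds. Not all 35 lists are printed for each comparison. Those printed, and Pecam1 in single libraries, were chosen after their values were seen, the lists with stability in view.

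Alternatives were DESeq2 size factors in edgeR, total count scaling, the DESeq2 1.42.0 Wald test, no filter, a fit on the compared groups alone, a replicate block, an added limit of 1 on the log2 fold change, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, removal of the 20 most abundant genes, and each library left out in turn. For lists, the estimated correlation and fry were tried as well. Leaving out LBDXL 3W 1 and BM 3W 2 together, and giving each comparison with BM 3W its own BM 3W library, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 in Python 3.11.15.

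The test of genes and lists was tested on simulated counts for LBDXL 3W against FH, with 200 of 11600 genes changed. It recovered 8% of the genes changed 2-fold, 75% at 4-fold and 94% at 8-fold, and called 6 unchanged genes.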

Results

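RNA was sequenced from mouse hepatocytes, the parenchymal cells of the liver, in 14 libraries that fell into 7 groups of 2. FH libraries came from freshly isolated hepatocytes and FH Yap-/- libraries from freshly isolated hepatocytes labelled Yap-/-. BM and LBDXL are the names the labels give to the cultured hepatocytes. BM cells were sampled at 1 day (BM 1D), 3 days (BM 3D) and 3 weeks (BM 3W), Yap-/- BM cells at 3 weeks (BM 3W Yap-/-) and LBDXL cells at 3 weeks (LBDXL 3W). The study's stated subject is whether limiting the activation of YAP by mechanical tension keeps hepatocyte functions in culture. Total counts ran from 15501005 to 21220365 per library.

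Levels below are TMM-scaled CPM, that is, counts relative to the scaled library size, as mean ± SD of 2 libraries, and log2 fold changes carry ± their standard error. "Rose" and "fell" are used for genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test over 14100 genes, and a pair "over the list alone" gives rises and falls adjusted over that list only. The labels do not say that the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples. The FH libraries differed by a chi-square of 5.53 per degree of freedom over their counts and the FH Yap-/- libraries by 4.06. In the 5 cultured groups this value lay between 68.5 and 237.

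Yap1, which encodes the transcriptional co-activator YAP (chromosome 9, 7931999 to 8004638 in GRCm38.p6, NCBI gene 22601), was lower in each of the 4 libraries labelled Yap-/-. It stood at 24.8 ± 2.37 CPM in FH Yap-/- against 92.6 ± 7.03 in FH, a log2 fold change of -1.90 ± 0.19 (adjusted p = 0.00130). In BM 3W Yap-/- it stood at 7.20 ± 0.770 CPM against 87.8 ± 10.8 in BM 3W, a log2 fold change of -3.61 ± 0.21 (adjusted p = 2.55e-05). Yap1 did not pass against FH in BM 1D (122 ± 12.9 CPM), BM 3D (111 ± 12.6) or LBDXL 3W (97.0 ± 1.01). Its test in BM 3W is not reported here under any scaling. By total counts Yap1 was higher in BM 1D (log2 1.32, adjusted p = 6.09e-04) and BM 3D (log2 1.22, 0.00109), and passed on both FPKM scales.

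**Figure D1:**
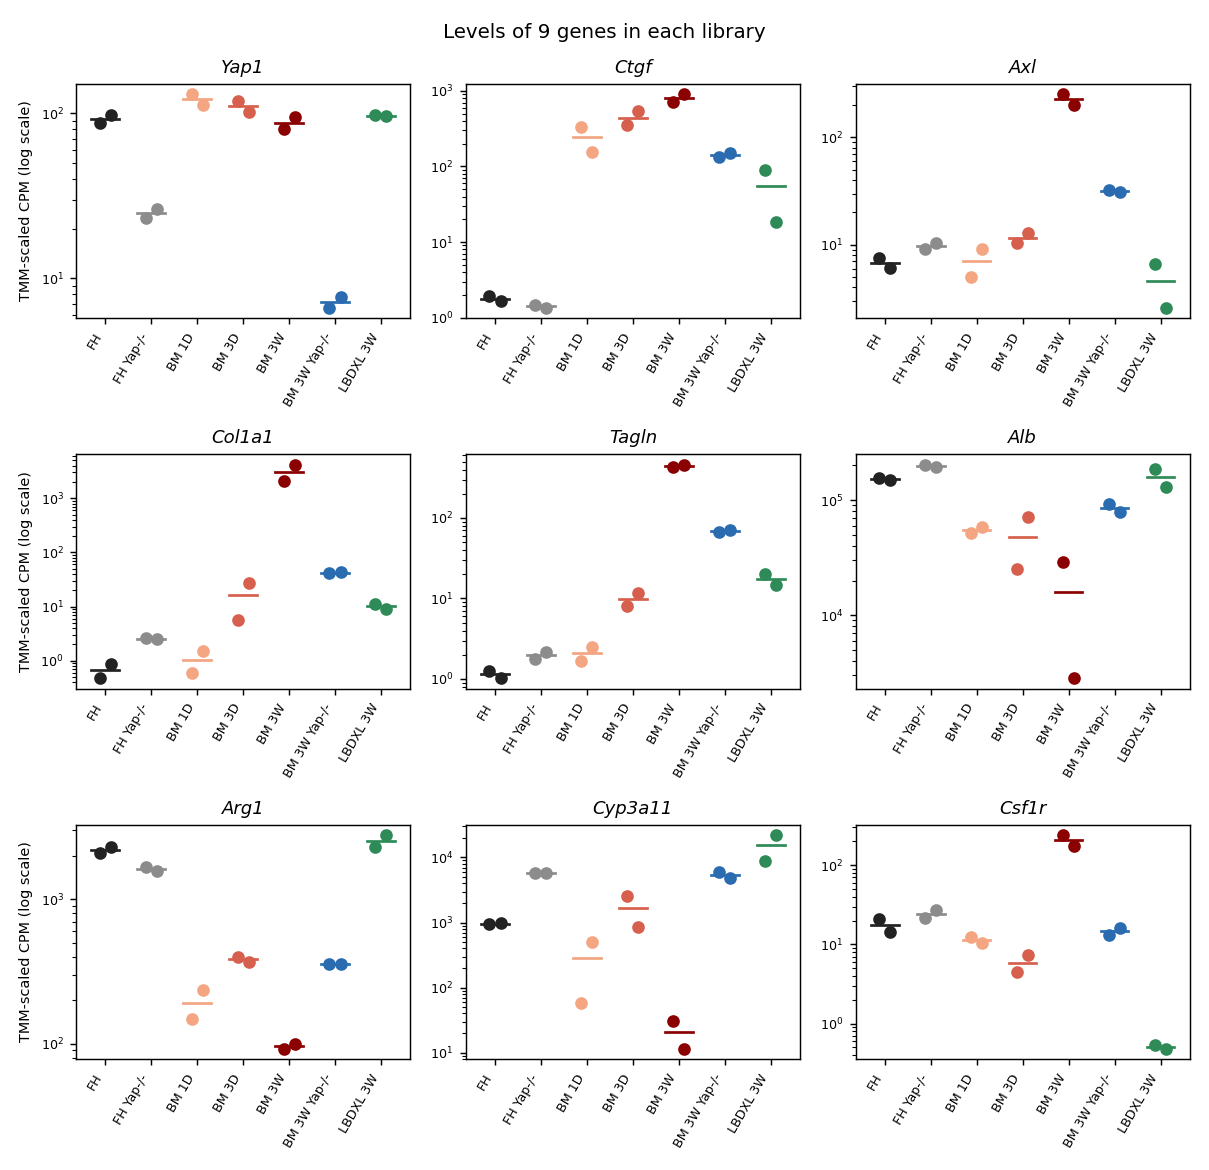
TMM-scaled CPM on a log axis (y) of 9 genes in each of the 14 libraries (points) by group (x), with the mean of the 2 libraries as a bar. Yap1 lies at 24.8 CPM in FH Yap-/- and 7.20 in BM 3W Yap-/- and at 87.8 or more in the other groups, while Ctgf, Col1a1, Tagln and Csf1r are highest in BM 3W.

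The first principal component held 52.9% of the variance and the second 16.2%. FH and FH Yap-/- libraries lay between -149.8 and -129.4 on the first component, BM 3W at 163.2 and 185.7, and BM 3W Yap-/- at 56.2. The LBDXL 3W libraries lay at 2.15 and -60.4. Pearson's r with the FH mean across genes, which are not independent replicates, was 0.61 and 0.66 in BM 3W, 0.82 and 0.83 in BM 3W Yap-/-, and 0.88 and 0.91 in LBDXL 3W.

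**Figure D2:**
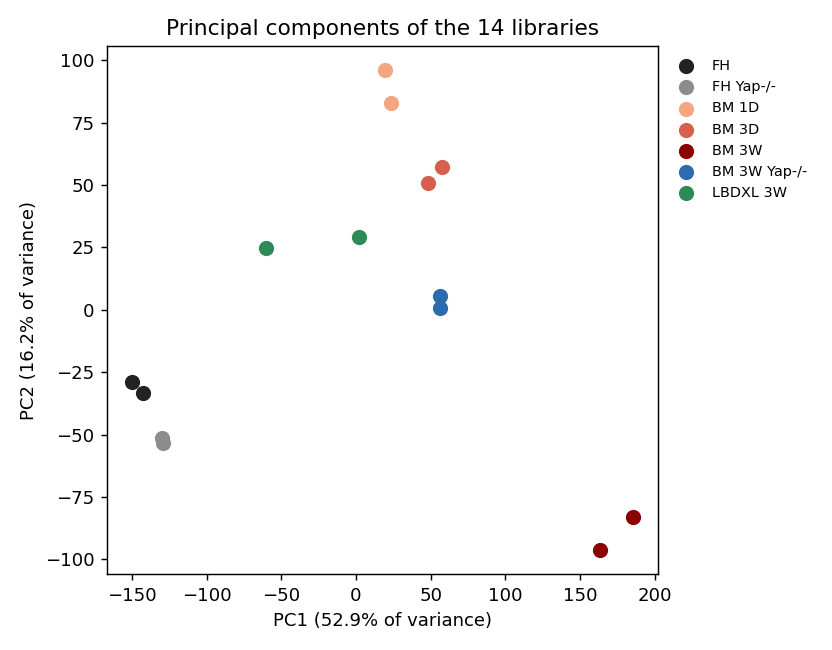
Positions of the 14 libraries (points, coloured by group) on the first (x, 52.9% of variance) and second (y, 16.2%) principal components of log2 CPM. The BM 3W libraries lie farthest from FH on the first component, at 163.2 and 185.7 against -142.7 and -149.8.

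The first question was what 1 day of BM culture did to the cells. Hepatocyte enzymes fell steeply while cytoskeletal genes and targets of p53 and NRF2 rose. Pck1, which commits carbon to gluconeogenesis, stood at 11.7 ± 0.801 against 6349.7 ± 107 CPM, a log2 fold change of -9.08 ± 1.05, and Keg1 at 0.998 ± 0.135 against 422 ± 14.4 CPM, log2 -8.72 ± 0.61. Ctgf, a secreted matricellular protein and a standard YAP target (chromosome 10, 24595442 to 24598683), rose to 245 ± 126 CPM from 1.78 ± 0.174 (log2 7.10 ± 0.77). Vim, an intermediate filament gene, reached 233 ± 0.537 against 3.09 ± 0.235 CPM, log2 6.23 ± 0.68. Cldn4, a tight junction gene that is also on the cholangiocyte list, had 0 counts in FH and was at least 494-fold higher at 118 ± 22.8 CPM.

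Of 20 genes of the urea cycle and amino acid catabolism, 0 rose, 19 fell and 1 did not pass (0 and 20 over the list alone). Their median log2 fold change was -4.82 (adjusted p = 6.31e-11, and adjusted p = 0.232 with an estimated correlation). Arg1, the last enzyme of the urea cycle, stood at log2 -3.52 ± 0.33 and Fah, of tyrosine breakdown, at log2 -3.61 ± 0.43. Of 19 bile acid genes, 0 rose, 18 fell and 1 did not pass (0 and 19 over the list alone). The list's median was -5.06 (adjusted p = 7.08e-10, and adjusted p = 0.232 with an estimated correlation). Among them were Akr1d1, a steroid reductase (log2 -6.48 ± 0.65), and Nr1h4, the bile acid receptor (log2 -3.79 ± 0.45). Of 20 phase II conjugation genes, 0 rose, 17 fell and 3 did not pass (0 and 18 over the list alone), with adjusted p = 2.4e-09, and adjusted p = 0.232 with an estimated correlation. Glyat, a glycine acyltransferase, was at log2 -3.96 ± 0.32 and Gsta3, a glutathione transferase, at log2 -4.01 ± 0.40. Of 20 fatty acid oxidation genes, 1 rose, 17 fell and 2 did not pass (1 and 18 over the list alone), with adjusted p = 1.12e-08, and adjusted p = 0.232 with an estimated correlation. Cpt1a, which admits fatty acids to mitochondria, was at log2 -4.43 ± 0.39.

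Among the genes that rose, actin cytoskeleton genes stood out by number. Of 25 tested, 21 rose, 0 fell and 4 did not pass (22 and 0 over the list alone), with adjusted p = 1.3e-09, and adjusted p = 0.251 with an estimated correlation. Tagln2 was at log2 4.68 ± 0.32, Actg1 at log2 3.67 ± 0.35, Tpm1, a tropomyosin, at log2 3.19 ± 0.32 and Actn1, an actinin, at log2 2.60 ± 0.28. Of 14 p53 targets and senescence genes, 11 rose, 0 fell and 3 did not pass (11 and 0 over the list alone, camera adjusted p = 4.84e-06, and adjusted p = 0.232 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by log2 7.49 ± 0.53 and Zmat3 by log2 2.61 ± 0.29. Of 14 NRF2 targets, 10 rose, 1 fell and 3 did not pass (10 and 1 over the list alone, camera adjusted p = 4.54e-04, and adjusted p = 0.308 with an estimated correlation), among them Hmox1, a haem oxygenase (log2 5.84 ± 0.53), and Srxn1, a sulfiredoxin (log2 4.84 ± 0.75). Of 21 YAP/TEAD targets, 12 rose, 0 fell and 9 did not pass (12 and 0 over the list alone), with adjusted p = 0.00576, and adjusted p = 0.476 with an estimated correlation. Of 18 interferon response genes, 10 rose, 0 fell and 8 did not pass (12 and 0 over the list alone), with adjusted p = 0.00298, and adjusted p = 0.457 with an estimated correlation, and the list did not pass without BM 1D 2 (adjusted p = 0.0575). Usp18, a protease of the interferon response, stood at log2 2.73 ± 0.42. Of 17 genes of the unfolded protein and integrated stress response, 8 rose, 5 fell and 4 did not pass (8 and 5 over the list alone), and the list did not pass (adjusted p = 0.535). For 16 cholangiocyte and progenitor markers, 7 rose, 2 fell and 7 did not pass (9 and 2 over the list alone), with a median of 2.83 (2.67 with genes at 0 set at their bound) (adjusted p = 0.0408, and adjusted p = 0.476 with an estimated correlation). The list did not pass by total counts alone (adjusted p = 0.330), with a replicate block (0.0533), without FH 2 (0.0586), BM 1D 2 (0.127) or either BM 3W Yap-/- library (0.0530). For 14 stellate cell and fibroblast markers, 0 rose, 5 fell and 9 did not pass (0 and 4 over the list alone), and the list did not pass (adjusted p = 0.0758).

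In BM 1D against FH 3328 genes rose and 2842 fell. Scaled by total counts alone the split was 7063 higher to 1351 lower, with a median shift of 0.92 on the log2 scale. The count was 3919 without FH 1 and 3842 without FH 2.

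After 3 days in BM culture hepatocyte enzymes stood below FH and cytoskeletal genes above it, while interferon response genes as a list did not pass (median log2 -0.14, adjusted p = 0.560). Cyp2e1, a cytochrome P450 of the pericentral hepatocyte (chromosome 7, 140763819 to 140774990), stood at 6.73 ± 3.16 against 20508 ± 772 CPM, log2 -11.57 ± 1.72. Ctgf was at 443 ± 130.2 against 1.78 ± 0.174 CPM, log2 7.95 ± 0.79, and Ankrd1, another YAP target, at 69.4 ± 50.4 CPM against 0.397 ± 0.114. Cdkn1a was at 147 ± 51.1 against 1.63 ± 0.174 CPM, log2 6.49 ± 0.51. Slc22a7, an organic anion transporter, had 0 counts in BM 3D and was at least 399-fold lower than its 59.0 ± 3.06 CPM in FH. Cyp2b10, a P450 induced through the nuclear receptor CAR, moved the other way, to 499.7 ± 254 against 1.63 ± 0.398 CPM, log2 8.26 ± 0.93.

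Of 25 actin cytoskeleton genes, 25 rose, 0 fell and 0 did not pass (25 and 0 over the list alone). Their median was 3.05 (adjusted p = 2.03e-11, and adjusted p = 0.207 with an estimated correlation). Tagln2 was at log2 5.52 ± 0.33, Tpm1 at log2 3.05 ± 0.32 and Myl12a, a myosin light chain, at log2 2.59 ± 0.27. Of 28 extracellular matrix and mesenchymal genes, 18 rose, 1 fell and 9 did not pass (21 and 1 over the list alone, camera adjusted p = 3.84e-06, and adjusted p = 0.290 with an estimated correlation). Vim was at log2 6.38 ± 0.69. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), was at 16.5 ± 15.3 against 0.674 ± 0.278 CPM, and its log2 fold change of 4.60 ± 0.79 was over 1.5 times smaller on the log2(FPKM + 1) scale. Of 14 stellate cell and fibroblast markers, 2 rose, 0 fell and 12 did not pass (1 and 0 over the list alone), with a median of 0.19. Of 16 cholangiocyte and progenitor markers, 10 rose, 0 fell and 6 did not pass (10 and 0 over the list alone), with a median of 3.38 (adjusted p = 7.62e-04, and adjusted p = 0.259 with an estimated correlation). Among 12 Kupffer cell and macrophage markers, 1 rose, 5 fell and 6 did not pass (1 and 5 over the list alone), with a median of -0.69 (adjusted p = 0.0433, and adjusted p = 0.279 with an estimated correlation). That call was lost with a replicate block (adjusted p = 0.0504), without FH 1 (0.108), without BM 3D 2 (0.142) and without any BM 3W or LBDXL 3W library (0.0511 to 0.0539, and 0.0661 without LBDXL 3W 1 and BM 3W 2 together). Of 21 YAP/TEAD targets, 16 rose, 0 fell and 5 did not pass (16 and 0 over the list alone, camera adjusted p = 3.7e-06, and adjusted p = 0.228 with an estimated correlation), among them Igfbp3, an IGF-binding protein (log2 5.23 ± 0.69). Of 21 proliferation genes, 18 rose, 0 fell and 3 did not pass (19 and 0 over the list alone, camera adjusted p = 6.57e-07, and adjusted p = 0.305 with an estimated correlation). Mcm2, a replication helicase subunit, was at 28.5 ± 17.9 against 1.07 ± 0.284 CPM.

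Of 15 pericentral Wnt targets, 0 rose, 13 fell and 2 did not pass (0 and 13 over the list alone), with adjusted p = 1.02e-09, and adjusted p = 0.0326 with an estimated correlation. Glul, glutamine synthetase, was at 109.9 ± 24.1 against 2225 ± 136 CPM, log2 -4.34 ± 0.34 and Lect2, a secreted hepatokine, at log2 -4.44 ± 0.49. Of 20 genes of the urea cycle and amino acid catabolism, 0 rose, 19 fell and 1 did not pass (0 and 19 over the list alone, camera adjusted p = 3.7e-11, and adjusted p = 0.207 with an estimated correlation). Ass1, argininosuccinate synthase, was at 245 ± 16.7 against 5115 ± 40.5 CPM, log2 -4.38 ± 0.58. Of 25 phase I genes, 1 rose, 18 fell and 6 did not pass (1 and 19 over the list alone, camera adjusted p = 3.11e-08, and adjusted p = 0.217 with an estimated correlation), and Cyp2b10 was the gene that rose. Aox3, an aldehyde oxidase, was at log2 -4.72 ± 0.62 and Ces1d, a carboxylesterase, at log2 -7.59 ± 1.04. Of 22 plasma protein genes, 0 rose, 16 fell and 6 did not pass (0 and 16 over the list alone), with adjusted p = 2.91e-05, and adjusted p = 0.354 with an estimated correlation. Apoa2, an apolipoprotein, was at log2 -4.98 ± 1.03 and Ttr, transthyretin, at log2 -2.88 ± 0.63. Alb, albumin (chromosome 5, 90460870 to 90476602), differed between the BM 3D libraries, at 25437.6 and 71033 CPM, and did not pass (log2 -1.66 ± 1.09, adjusted p = 0.243), though it did with DESeq2 (adjusted p = 0.0486). Of 16 circadian clock genes, 2 rose, 9 fell and 5 did not pass (2 and 9 over the list alone, camera adjusted p = 0.00277, and adjusted p = 0.207 with an estimated correlation).

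In BM 3D against FH 3175 genes rose and 2530 fell. By total counts alone 7575 were higher and 1038 lower, with a median shift of 0.94. Without FH 1 the count was 3555 and without FH 2 3435.

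From BM 1D to BM 3D fewer genes moved, and those named here passed only when all groups shared the estimate of spread. Dhx58, an interferon-induced RNA sensor, fell to 6.28 ± 1.15 against 31.0 ± 10.7 CPM (log2 -2.30 ± 0.36), with an adjusted p of 0.117 in the fit on these 4 libraries. Of 18 interferon response genes, 1 rose, 8 fell and 9 did not pass (1 and 15 over the list alone), with adjusted p = 1.74e-09, and adjusted p = 0.710 with an estimated correlation. Of 21 proliferation genes, 11 rose, 0 fell and 10 did not pass (11 and 0 over the list alone, camera adjusted p = 9.69e-07, and adjusted p = 0.710 with an estimated correlation). Among 28 extracellular matrix and mesenchymal genes, 5 rose, 0 fell and 23 did not pass (7 and 0 over the list alone, camera adjusted p = 5.57e-05, and adjusted p = 0.710 with an estimated correlation). For 14 stellate cell and fibroblast markers, 2 rose, 0 fell and 12 did not pass (5 and 0 over the list alone), with a median of 1.63 (adjusted p = 0.00255, and adjusted p = 0.710 with an estimated correlation), a call lost without BM 1D 1 (adjusted p = 0.0623) or BM 3D 2 (0.362). In this comparison 517 genes rose and 225 fell. A fit on these 4 libraries alone called 0 of 12512 genes by edgeR, with 1819 at an unadjusted p under 0.05, and DESeq2 called 1750 in the fit of all libraries. The count was 178 without BM 1D 1, 404 without BM 3D 1, 435 and 433 without FH 1 or FH 2, 413 and 416 without FH Yap-/- 1 or 2, and 1206 and 1210 without LBDXL 3W 1 or 2.

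At 3 weeks in BM culture, the collagen genes named here stood far above FH and hepatocyte genes far below it. Col1a1 stood at 3128 ± 1466 against 0.674 ± 0.278 CPM, log2 12.17 ± 1.00, and Spp1, osteopontin, at 4687 ± 495 against 23.5 ± 2.44 CPM, log2 7.64 ± 0.83. Ctgf reached 810.3 ± 129 against 1.78 ± 0.174 CPM, log2 8.82 ± 0.82 and Ankrd1 214 ± 31.7 CPM against 0.397 ± 0.114. Pck1 stood at 0.319 ± 0.0147 against 6349.7 ± 107 CPM, log2 -14.25 ± 1.27 and Cyp3a11, a main drug-metabolising P450 (chromosome 5, 145854607 to 145879854), at 21.0 ± 13.4 against 965 ± 23.2 CPM, log2 -5.52 ± 1.07. Hnf4a, a nuclear receptor that maintains hepatocyte identity, was at 168 ± 46.4 against 1061 ± 5.39 CPM (log2 -2.66 ± 0.33), a fall over 1.5 times smaller under total count scaling and on FPKM. Afp, alpha-fetoprotein, was at 526 ± 377 against 2.06 ± 0.217 CPM, log2 7.99 ± 1.04.

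Of 20 genes of the urea cycle and amino acid catabolism, 0 rose, 20 fell and 0 did not pass (0 and 20 over the list alone). Their median was -7.06 (adjusted p = 2.32e-11, and adjusted p = 0.183 with an estimated correlation). Arg1 was at log2 -4.51 ± 0.34 and Aass, of lysine breakdown, at log2 -7.94 ± 0.80. Of 22 plasma protein genes, 0 rose, 22 fell and 0 did not pass (0 and 22 over the list alone, camera adjusted p = 1.15e-07, and adjusted p = 0.247 with an estimated correlation). Serpinc1, antithrombin, was at log2 -5.75 ± 0.91 and F9, a clotting factor, at log2 -4.29 ± 0.53. Of 25 phase I genes, 0 rose, 23 fell and 2 did not pass (0 and 23 over the list alone, camera adjusted p = 2.32e-10, and adjusted p = 0.183 with an estimated correlation). Por, the electron donor of microsomal P450s, was at 74.5 ± 2.27 against 1558 ± 27.9 CPM, log2 -4.39 ± 0.30. Cyp2f2, a periportal P450, stood at log2 -11.86 ± 1.02. Of 19 bile acid genes, 0 rose, 19 fell and 0 did not pass (0 and 19 over the list alone, camera adjusted p = 1.16e-09, and adjusted p = 0.183 with an estimated correlation), among them Cyp27a1, a sterol hydroxylase (log2 -5.89 ± 0.54). Of 15 pericentral Wnt targets, 1 rose, 9 fell and 5 did not pass (1 and 9 over the list alone, camera adjusted p = 0.00259, and adjusted p = 0.183 with an estimated correlation). Glul was at log2 -4.66 ± 0.35.

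Of 28 extracellular matrix and mesenchymal genes, 23 rose, 0 fell and 5 did not pass (23 and 0 over the list alone), and their median was 7.95 (7.66 with genes at 0 set at their bound) (adjusted p = 5.55e-09, and adjusted p = 0.183 with an estimated correlation). Col1a2, the partner chain of Col1a1, was at 2972 ± 1298 against 3.17 ± 0.908 CPM, log2 9.87 ± 0.81 and Col5a1 at log2 8.51 ± 0.68. Of 25 actin cytoskeleton genes, 24 rose, 0 fell and 1 did not pass (24 and 0 over the list alone, camera adjusted p = 1.38e-09, and adjusted p = 0.183 with an estimated correlation). Tagln, a smooth muscle actin-binding protein, was at 447 ± 15.7 against 1.15 ± 0.172 CPM, log2 8.59 ± 0.35. Of 21 YAP/TEAD targets, 19 rose, 1 fell and 1 did not pass (19 and 1 over the list alone, camera adjusted p = 5.43e-06, and adjusted p = 0.183 with an estimated correlation). Axl, a receptor tyrosine kinase, was at log2 5.06 ± 0.44. Of 10 fetal liver genes, 9 rose, 0 fell and 1 did not pass (9 and 0 over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.201 with an estimated correlation). Of 14 p53 targets and senescence genes, 13 rose, 0 fell and 1 did not pass (13 and 0 over the list alone, camera adjusted p = 1.4e-05, and adjusted p = 0.183 with an estimated correlation).

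Markers of other liver cells rose in the same libraries. Of 14 stellate cell and fibroblast markers, 12 rose, 0 fell and 2 did not pass (13 and 0 over the list alone, camera adjusted p = 1.6e-04, and adjusted p = 0.304 with an estimated correlation). Lum, lumican, was at 439 ± 239.5 against 2.90 ± 0.963 CPM, log2 7.24 ± 0.58 and Pdgfrb, a mesenchymal growth factor receptor, at log2 6.24 ± 0.50. Of 12 Kupffer cell and macrophage markers, 10 rose, 2 fell and 0 did not pass (10 and 2 over the list alone, camera adjusted p = 0.0108, and adjusted p = 0.183 with an estimated correlation), and the list did not pass under total count scaling (adjusted p = 0.221). Csf1r, the receptor for macrophage colony-stimulating factor, was at 206 ± 46.1 against 17.7 ± 4.55 CPM, log2 3.54 ± 0.30 and C1qa at log2 4.10 ± 0.35. Of 16 cholangiocyte and progenitor markers, 14 rose, 0 fell and 2 did not pass (15 and 0 over the list alone, camera adjusted p = 1.06e-04, and adjusted p = 0.183 with an estimated correlation). Sox9 was at log2 3.98 ± 0.63. Ptprc, the pan-leukocyte antigen, was at 40.1 ± 16.6 against 3.29 ± 0.628 CPM, log2 3.60 ± 0.44. Of 14 sinusoidal endothelial markers, 2 rose, 7 fell and 5 did not pass (2 and 8 over the list alone), with a median of -2.55 that did not pass (adjusted p = 0.146).

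In BM 3W against FH 4653 genes rose and 3675 fell, and by total counts alone 9280 were higher and 1364 lower, with a median shift of 1.29. The BM 3W libraries differed in Alb, at 29178 CPM in BM 3W 1 and 2849 in BM 3W 2, and Alb passed (log2 -3.25 ± 1.16, adjusted p = 0.0315) but not without FH 1 (0.0719), FH 2 (0.0691) or BM 3W Yap-/- 2 (0.0552). It did not pass under total count scaling (0.0683) or in the fit on these 4 libraries (0.134) either.

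**Figure D3:**
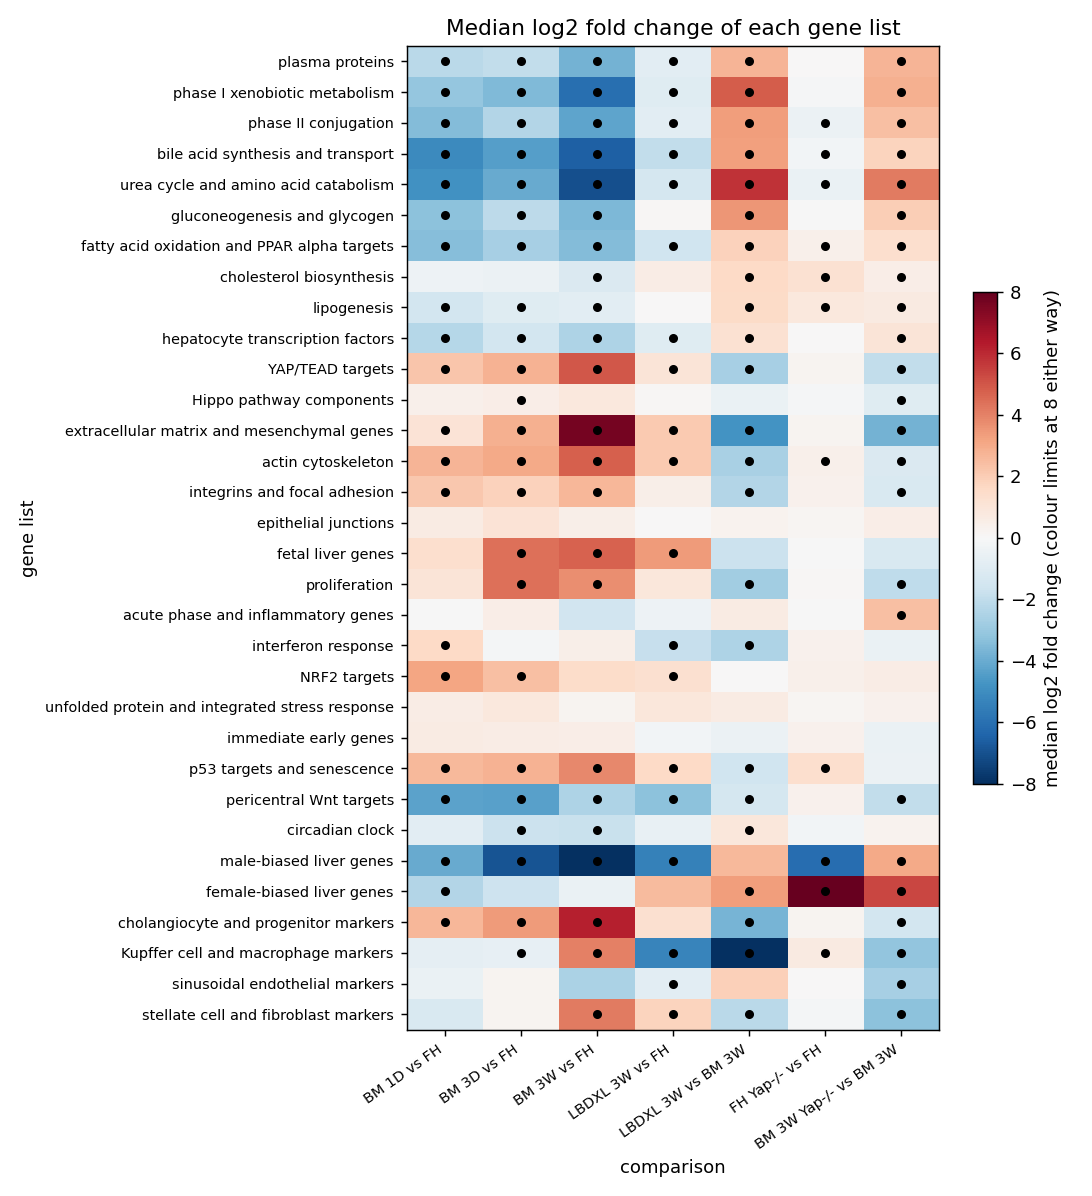
Median log2 fold change (colour) of 32 gene lists (y) in 7 comparisons (x), with genes at 0 counts in a group set at their bound, and black dots for lists with a camera adjusted p under 0.05 at the preset correlation. The urea cycle and amino acid catabolism list lies at -7.06 in BM 3W against FH and at 5.77 in LBDXL 3W against BM 3W.

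Between BM 3D and BM 3W matrix genes rose and many hepatocyte enzymes fell. Col1a1 rose from 16.5 ± 15.3 to 3128 ± 1466 CPM (log2 7.57 ± 0.81), and Acta2, smooth muscle actin, stood at 721 ± 134 against 8.49 ± 2.90 CPM, log2 6.41 ± 0.59. Cyp3a11 fell to 21.0 ± 13.4 against 1698 ± 1215 CPM, log2 -6.34 ± 1.11. Cyp2b10, high at 3 days, was at 0.736 ± 0.653 against 499.7 ± 254 CPM, log2 -9.38 ± 0.97. Cps1, the entry enzyme of the urea cycle, was at 40.8 ± 44.8 against 2735 ± 1482 CPM, log2 -6.07 ± 0.95. Csf1r was at 206 ± 46.1 against 5.87 ± 2.0 CPM, log2 5.14 ± 0.33.

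Of 28 extracellular matrix and mesenchymal genes, 18 rose, 0 fell and 10 did not pass (19 and 0 over the list alone, camera adjusted p = 1.94e-09, and adjusted p = 0.360 with an estimated correlation). Among 20 genes of the urea cycle and amino acid catabolism, 0 rose, 16 fell and 4 did not pass (1 and 18 over the list alone, camera adjusted p = 7.33e-08, and adjusted p = 0.377 with an estimated correlation). Of 20 phase II conjugation genes, 0 rose, 13 fell and 7 did not pass (0 and 15 over the list alone, camera adjusted p = 2.51e-06, and adjusted p = 0.360 with an estimated correlation). Sult1a1, a sulfotransferase, was at log2 -4.43 ± 0.67. Of 14 stellate cell and fibroblast markers, 12 rose, 0 fell and 2 did not pass (12 and 0 over the list alone, camera adjusted p = 2.22e-08, and adjusted p = 0.360 with an estimated correlation). Lum was at log2 7.13 ± 0.57 and Cygb, cytoglobin, at log2 5.31 ± 0.64. Of 12 Kupffer cell and macrophage markers, 10 rose, 1 fell and 1 did not pass (10 and 1 over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.173 with an estimated correlation). C1qb was at log2 4.70 ± 0.39. Of 15 pericentral Wnt targets, 9 rose, 1 fell and 5 did not pass (9 and 1 over the list alone, camera adjusted p = 0.00133, and adjusted p = 0.173 with an estimated correlation), and Nkd1, a feedback inhibitor of Wnt signalling, was at 8.91 ± 2.77 against 0.314 ± 0.0433 CPM, log2 4.80 ± 0.48. Orm1, an acute phase plasma protein, was at log2 -4.55 ± 0.82 and Cgn, a tight junction protein, at log2 -2.30 ± 0.25.

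In all 1906 genes rose and 1541 fell from BM 3D to BM 3W. The split was 2092 to 1069 with DESeq2 size factors in edgeR and 2539 to 704 by total counts alone, whose median shift was 0.34. The count was 2198 without BM 3D 1, 2099 without BM 3W 1 and 1664 without BM 3W 2.

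LBDXL cells at 3 weeks were set beside FH to ask how close their transcripts stayed to fresh cells. Alb stood at 158331 ± 40334 against 152472 ± 3661 CPM (log2 0.05 ± 1.06, adjusted p = 0.997) and Hnf4a at 956 ± 52.6 against 1061 ± 5.39 CPM (log2 -0.15 ± 0.31, adjusted p = 0.776). Of the 18 hepatocyte transcription factors that include Hnf4a, 0 rose, 6 fell and 12 did not pass (1 and 8 over the list alone), with a median of -0.95 (adjusted p = 0.00166, and adjusted p = 0.371 with an estimated correlation). Cyp2b10 was far above FH, at 3523 ± 1167 against 1.63 ± 0.398 CPM, log2 11.08 ± 1.03. Cyp3a11 was at 15339 ± 9351 against 965 ± 23.2 CPM, log2 3.99 ± 0.99, a call lost without FH 1 (adjusted p = 0.118) or FH 2 (0.114). Cyp2e1 was low at 137 ± 157 against 20508 ± 772 CPM, log2 -7.22 ± 1.45, and Ces3a, a carboxylesterase, at 3.07 ± 2.32 against 3406 ± 8.80 CPM, log2 -10.12 ± 0.98. Ctgf was above FH at 54.3 ± 50.4 against 1.78 ± 0.174 CPM, log2 4.92 ± 0.70.

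Of 20 genes of the urea cycle and amino acid catabolism, 0 rose, 7 fell and 13 did not pass (0 and 9 over the list alone). Their median was -1.41 (adjusted p = 2.57e-05, and adjusted p = 0.453 with an estimated correlation). Of 22 plasma protein genes, 0 rose, 3 fell and 19 did not pass (0 and 2 over the list alone, camera adjusted p = 0.00787, and adjusted p = 0.657 with an estimated correlation). Of 20 fatty acid oxidation genes, 1 rose, 14 fell and 5 did not pass (1 and 16 over the list alone, camera adjusted p = 3.65e-08, and adjusted p = 0.318 with an estimated correlation), among them Cpt1a at log2 -2.59 ± 0.36, Hadha at log2 -1.55 ± 0.29 and Ppara, the nuclear receptor of this list, at log2 -3.0 ± 0.58. Of 19 bile acid genes, 0 rose, 9 fell and 10 did not pass (0 and 11 over the list alone, camera adjusted p = 7.76e-08, and adjusted p = 0.318 with an estimated correlation). Of 15 gluconeogenesis and glycogen genes, 0 rose, 1 fell and 14 did not pass (0 and 1 over the list alone), and the list did not pass (adjusted p = 0.297). Of 15 pericentral Wnt targets, 0 rose, 13 fell and 2 did not pass (0 and 14 over the list alone), with adjusted p = 3.45e-12, and adjusted p = 0.0135 with an estimated correlation, and Glul was at 295 ± 42.6 against 2225 ± 136 CPM, log2 -2.92 ± 0.32.

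Of 25 actin cytoskeleton genes, 15 rose, 0 fell and 10 did not pass (17 and 0 over the list alone, camera adjusted p = 7.54e-09, and adjusted p = 0.318 with an estimated correlation). Tagln2 was at log2 4.08 ± 0.31, Tagln at log2 3.90 ± 0.31 and Tpm1 at log2 2.15 ± 0.31. Of 28 extracellular matrix and mesenchymal genes, 15 rose, 1 fell and 12 did not pass (15 and 1 over the list alone, camera adjusted p = 1.96e-04, and adjusted p = 0.488 with an estimated correlation). Of 21 YAP/TEAD targets, 9 rose, 1 fell and 11 did not pass (10 and 1 over the list alone, camera adjusted p = 0.00283, and adjusted p = 0.488 with an estimated correlation), and the list did not pass without LBDXL 3W 1 (adjusted p = 0.0597). Of 14 p53 targets and senescence genes, 10 rose, 0 fell and 4 did not pass (11 and 0 over the list alone, camera adjusted p = 1.07e-05, and adjusted p = 0.318 with an estimated correlation). Cdkn1a was at 174 ± 101 against 1.63 ± 0.174 CPM, log2 6.74 ± 0.51. Of 18 interferon response genes, 0 rose, 11 fell and 7 did not pass (1 and 12 over the list alone, camera adjusted p = 2.14e-05, and adjusted p = 0.369 with an estimated correlation). Of 14 NRF2 targets, 7 rose, 0 fell and 7 did not pass (7 and 0 over the list alone, camera adjusted p = 0.00192, and adjusted p = 0.451 with an estimated correlation). Gstm3, a glutathione transferase, was at 3807 ± 2569 against 86.1 ± 0.408 CPM, log2 5.47 ± 0.73 and Pgd, of the pentose phosphate pathway, at log2 2.45 ± 0.40.

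Of 12 Kupffer cell and macrophage markers, 0 rose, 10 fell and 2 did not pass (0 and 11 over the list alone), with adjusted p = 1.19e-11, and adjusted p = 0.0209 with an estimated correlation. Clec4f, a Kupffer cell lectin, had 0 counts in LBDXL 3W and was at least 122-fold lower than its 22.2 ± 7.20 CPM in FH. Of 14 sinusoidal endothelial markers, 0 rose, 2 fell and 12 did not pass (0 and 2 over the list alone, camera adjusted p = 0.0266, and adjusted p = 0.675 with an estimated correlation). The LBDXL 3W libraries differed in them, and without LBDXL 3W 2 the list's direction turned upward (adjusted p = 0.634). Pecam1, an endothelial adhesion molecule, stood at 31 CPM in LBDXL 3W 1 and 0.785 in LBDXL 3W 2. Of 14 stellate cell and fibroblast markers, 7 rose, 0 fell and 7 did not pass (8 and 0 over the list alone, camera adjusted p = 0.00363, and adjusted p = 0.537 with an estimated correlation), a call lost without LBDXL 3W 1 (adjusted p = 0.0736).

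LBDXL 3W 1 had 0 counts of the 4 Y-linked genes tested and LBDXL 3W 2 306 to 1704, and sex-biased lists are given for that reason. Of 9 male-biased liver genes, 0 rose, 8 fell and 1 did not pass (0 and 8 over the list alone), with a median of -5.38 (adjusted p = 3.94e-08, and adjusted p = 0.212 with an estimated correlation). In BM 3D, where both libraries held Y-linked transcripts, the same list fell to a median of -6.88 (adjusted p = 3.72e-06, and adjusted p = 0.207 with an estimated correlation). Of 12 female-biased genes, 3 rose, 0 fell and 9 did not pass (6 and 1 over the list alone), and the list did not pass (adjusted p = 0.195). Among the sex chromosome genes none passed, and the list was lower (adjusted p = 0.0387, and adjusted p = 0.537 with an estimated correlation). That call was lost without LBDXL 3W 1 (adjusted p = 0.110) and without FH 2 or any BM library (0.0513 to 0.0566).

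In LBDXL 3W against FH 1655 genes rose and 1353 fell, and by total counts alone 3593 were higher and 823 lower, with a median shift of 0.47. A fit on these 4 libraries alone called 794 higher and 960 lower. The count was 1213 without FH 1, 1178 without FH 2 and 1853 without LBDXL 3W 1. With LBDXL 3W 1 and BM 3W 2 both left out it was 1830.

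The central comparison set LBDXL 3W against BM 3W at the same age. Hepatocyte enzymes were higher in LBDXL cells and matrix, cytoskeletal and macrophage genes lower. Cyp3a11 stood at 15339 ± 9351 against 21.0 ± 13.4 CPM, log2 9.51 ± 1.27, Arg1 at 2535 ± 341 against 96.2 ± 4.67 CPM, log2 4.72 ± 0.35 and Hnf4a at 956 ± 52.6 against 168 ± 46.4 CPM, log2 2.51 ± 0.33. Cyp2b10 (chromosome 7, 25897658 to 25926624) stood at 3523 ± 1167 against 0.736 ± 0.653 CPM, log2 12.20 ± 1.07 and Cyp2f2 at 1101 ± 1076 against 0.695 ± 0.499 CPM, log2 10.60 ± 0.97. Col1a1 stood at 10.2 ± 1.55 against 3128 ± 1466 CPM, log2 -8.27 ± 0.84, Ctgf at 54.3 ± 50.4 against 810.3 ± 129 CPM, log2 -3.90 ± 0.64, Ankrd1 at 18.2 ± 17.0 against 214 ± 31.7 CPM, log2 -3.55 ± 0.73 and Spp1 at 12.4 ± 3.93 against 4687 ± 495 CPM, log2 -8.56 ± 0.86. Yap1 itself was at 97.0 ± 1.01 against 87.8 ± 10.8 CPM (log2 0.14 ± 0.18, adjusted p = 0.555). Its sign turned with the scaling, to log2 -0.69 by total counts alone (adjusted p = 0.0247), -0.66 on log2(FPKM + 1) (0.0178) and -0.69 on log2(FPKM + 0.1) (0.0209).

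In the urea cycle and amino acid catabolism list of 20, 19 rose, 0 fell and 1 did not pass (19 and 0 over the list alone). Their median was 5.77 (adjusted p = 2.22e-11, and adjusted p = 0.197 with an estimated correlation). Ass1 was at log2 6.07 ± 0.63, Uroc1, of histidine breakdown, at log2 6.00 ± 0.71 and Fah at log2 3.62 ± 0.43. Of 25 phase I genes, 22 rose, 0 fell and 3 did not pass (22 and 0 over the list alone, camera adjusted p = 2.23e-10, and adjusted p = 0.197 with an estimated correlation). Por was at log2 3.24 ± 0.28. Of 20 phase II conjugation genes, 18 rose, 0 fell and 2 did not pass (18 and 0 over the list alone, camera adjusted p = 1.09e-08, and adjusted p = 0.197 with an estimated correlation). Sult1d1, a sulfotransferase, was at log2 6.21 ± 0.58 and Glyat at log2 3.31 ± 0.31. Of 22 plasma protein genes, 20 rose, 0 fell and 2 did not pass (21 and 0 over the list alone, camera adjusted p = 3.89e-07, and adjusted p = 0.258 with an estimated correlation). F9 was at log2 4.0 ± 0.52 and Apoc3, an apolipoprotein, at log2 4.89 ± 0.88. Of 15 gluconeogenesis and glycogen genes, 14 rose, 0 fell and 1 did not pass (14 and 0 over the list alone, camera adjusted p = 5.31e-08, and adjusted p = 0.197 with an estimated correlation). Khk, ketohexokinase, was at log2 4.51 ± 0.42. Of 21 cholesterol biosynthesis genes, 18 rose, 0 fell and 3 did not pass (19 and 0 over the list alone, camera adjusted p = 9.54e-07, and adjusted p = 0.258 with an estimated correlation). Of 15 lipogenesis genes, 8 rose, 0 fell and 7 did not pass (8 and 0 over the list alone, camera adjusted p = 1.83e-05, and adjusted p = 0.197 with an estimated correlation). Thrsp was at log2 6.53 ± 0.66.

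Among 21 YAP/TEAD targets, 0 rose, 18 fell and 3 did not pass (2 and 18 over the list alone, camera adjusted p = 1.11e-05, and adjusted p = 0.224 with an estimated correlation). Axl was at log2 -5.61 ± 0.45 and Ccdc80 at log2 -6.54 ± 0.94. For 28 extracellular matrix and mesenchymal genes, 0 rose, 22 fell and 6 did not pass (0 and 23 over the list alone, camera adjusted p = 5.37e-10, and adjusted p = 0.224 with an estimated correlation). Col1a2 was at log2 -7.66 ± 0.74 and Vim at log2 -4.91 ± 0.63. Of 25 actin cytoskeleton genes, 0 rose, 21 fell and 4 did not pass (0 and 21 over the list alone, camera adjusted p = 1.13e-07, and adjusted p = 0.224 with an estimated correlation). Tagln was at log2 -4.69 ± 0.28, Acta2 at log2 -5.89 ± 0.57 and Actn1 at log2 -3.44 ± 0.29. Of 20 integrin and focal adhesion genes, 0 rose, 16 fell and 4 did not pass (0 and 16 over the list alone, camera adjusted p = 1.22e-06, and adjusted p = 0.197 with an estimated correlation). Lamc1, a laminin chain, was at log2 -1.68 ± 0.27. Of 21 proliferation genes, 0 rose, 17 fell and 4 did not pass (0 and 17 over the list alone, camera adjusted p = 7.74e-05, and adjusted p = 0.407 with an estimated correlation). Ccnd1, cyclin D1, was at log2 -4.08 ± 0.69.

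Markers of other cells differed too, so hepatocyte change was not separated from cell mixture. Of 12 Kupffer cell and macrophage markers, 0 rose, 10 fell and 2 did not pass (0 and 11 over the list alone, camera adjusted p = 1.09e-08, and adjusted p = 0.110 with an estimated correlation). Csf1r was at 0.506 ± 0.0320 against 206 ± 46.1 CPM, log2 -8.65 ± 0.40. Of 14 stellate cell and fibroblast markers, 0 rose, 10 fell and 4 did not pass (0 and 10 over the list alone, camera adjusted p = 3.99e-04, and adjusted p = 0.318 with an estimated correlation). Lum was at log2 -4.86 ± 0.51 and Pdgfrb at log2 -3.86 ± 0.43. Of 16 cholangiocyte and progenitor markers, 0 rose, 14 fell and 2 did not pass (0 and 14 over the list alone, camera adjusted p = 1.83e-05, and adjusted p = 0.215 with an estimated correlation). Sox9 was at log2 -2.96 ± 0.59. Of 12 female-biased liver genes, 7 rose, 0 fell and 5 did not pass (7 and 0 over the list alone, camera adjusted p = 0.0244, and adjusted p = 0.258 with an estimated correlation). That call was lost without LBDXL 3W 1 (adjusted p = 0.0538), which lacked Y-linked transcripts, and without BM 3W 2 (0.0647). Of 9 male-biased genes, 5 rose, 0 fell and 4 did not pass (5 and 0 over the list alone), and the list did not pass (adjusted p = 0.0743).

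In LBDXL 3W against BM 3W 2980 genes were higher and 3343 lower. By total counts alone 1135 were higher and 6649 lower, with a median shift of -0.82, and DESeq2 size factors shifted genes by -0.15. The fit on these 4 libraries alone called 3997 genes, and the count was 4156 without BM 3W 2 and 3993 without LBDXL 3W 2.

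Of the 3175 genes that rose in BM 3D against FH, 1485 (46.8%) were lower in LBDXL 3W than in BM 3W and 153 were higher. Of the 2530 that fell, 1532 (60.6%) were higher in LBDXL 3W and 159 lower. Among genes called in both comparisons 90.6% moved the opposite way. The median log2 difference from FH of the 3175 genes was 1.89 in BM 3W, 1.40 in BM 3W Yap-/- and 0.91 in LBDXL 3W. For the 2530 genes it was -1.86, -1.29 and -0.83.

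FH Yap-/- cells were set beside FH to measure how Yap-/- cells differed before culture. Few genes passed in the fit of all groups, and genes whose liver expression differs between the sexes led them. Cyp2b13, a P450 of female mouse liver, had 0 counts in FH and was at least 2850.0-fold higher at 679.6 ± 25 CPM. Slco1a1, a transporter of male mouse liver, stood at 29.5 ± 0.0312 against 1206 ± 17.4 CPM, log2 -5.35 ± 0.73. The call of Slco1a1 was lost without FH Yap-/- 1 (adjusted p = 0.154) or FH Yap-/- 2 (0.168). Of 12 female-biased liver genes, 11 rose, 0 fell and 1 did not pass (11 and 0 over the list alone), with adjusted p = 7.25e-39, and adjusted p = 0.00162 with an estimated correlation. Of 9 male-biased genes, 0 rose, 7 fell and 2 did not pass (0 and 9 over the list alone), with adjusted p = 3.19e-25, and adjusted p = 0.0189 with an estimated correlation. The 4 Y-linked genes tested had 0 or 1 count in each FH Yap-/- library and 408 to 2015 in each FH library. Ddx3y was thus at least 657-fold lower, although none of the 4 passed over all genes tested (adjusted p for Ddx3y 0.0894) and all 4 did adjusted over the list alone. Ddx3y passed with DESeq2 (adjusted p = 3.03e-25), in the fit on these 4 libraries, without a filter and without LBDXL 3W 1 (3.63e-07) or LBDXL 3W 2 (3.39e-07). The same Y-linked genes were at 0 in LBDXL 3W 1 and at 254 counts or more in the other 11 libraries.

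Genotype and sex could not be separated in this comparison. Beyond these lists, some lipid synthesis and p53 target genes were higher in FH Yap-/-, though most members did not pass and the list calls were lost with an estimated correlation. Of 21 cholesterol biosynthesis genes, 3 rose, 0 fell and 18 did not pass (13 and 0 over the list alone, camera adjusted p = 1.94e-16, and adjusted p = 0.177 with an estimated correlation). Of 15 lipogenesis genes, 4 rose, 0 fell and 11 did not pass (7 and 0 over the list alone, camera adjusted p = 3.43e-09, and adjusted p = 0.0605 with an estimated correlation). Fasn, fatty acid synthase, was at 2116 ± 32.4 against 293 ± 6.95 CPM, log2 2.85 ± 0.38. Of 14 p53 targets and senescence genes, 3 rose, 0 fell and 11 did not pass (7 and 0 over the list alone, camera adjusted p = 1.95e-11, and adjusted p = 0.0800 with an estimated correlation). Cdkn1a was at 26.9 ± 0.0193 against 1.63 ± 0.174 CPM, log2 4.04 ± 0.47 and Eda2r, a p53-induced receptor, at 7.08 ± 0.161 against 0.159 ± 5.45e-04 CPM, log2 5.42 ± 0.66. Some hepatocyte lists were lower. Of 20 phase II conjugation genes, 0 rose, 1 fell and 19 did not pass (0 and 2 over the list alone, camera adjusted p = 5.47e-04, and adjusted p = 0.597 with an estimated correlation), of 20 urea cycle and amino acid genes, 0 rose, 0 fell and 20 did not pass (0 and 0 over the list alone, camera adjusted p = 0.00943, and adjusted p = 0.900 with an estimated correlation), and of 19 bile acid genes, 0 rose, 2 fell and 17 did not pass (0 and 2 over the list alone, camera adjusted p = 0.0173, and adjusted p = 0.900 with an estimated correlation). Of 21 YAP/TEAD targets, 0 rose, 0 fell and 21 did not pass (1 and 1 over the list alone), and the list did not pass (adjusted p = 0.842). Ctgf was at 1.40 ± 0.0634 against 1.78 ± 0.174 CPM (log2 -0.34 ± 0.71). Markers of white blood cells and macrophages were higher as lists, though no single marker passed over all genes. Of 5 leukocyte markers, 0 rose, 0 fell and 5 did not pass (2 and 0 over the list alone), with a median of 1.31 (adjusted p = 2.87e-05, and adjusted p = 0.0605 with an estimated correlation). Among 12 Kupffer cell and macrophage markers, 0 rose, 0 fell and 12 did not pass (0 and 0 over the list alone), with a median of 0.74 (adjusted p = 0.00400, and adjusted p = 0.210 with an estimated correlation), a call lost without FH 2 (adjusted p = 0.0997).

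The call of Fasn was lost without any of the 4 fresh libraries (adjusted p up to 0.146), and those of Cdkn1a and Eda2r without FH 1 (0.0544 and 0.0797) or FH 2 (0.0790 and 0.0925). Eda2r was not called on log2(FPKM + 1) (0.485) either.

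In FH Yap-/- against FH 69 genes rose and 64 fell in the fit of all groups. The 4 fresh libraries alone gave 2050 and 2201, and DESeq2 gave 208 and 166. The count was 21 without FH 1, 22 without FH 2, 17 without FH Yap-/- 1, 13 without FH Yap-/- 2, 80 without BM 3W Yap-/- 1, and 231 without LBDXL 3W 1 or without LBDXL 3W 2. Of the 28 called genes that the naming rule made eligible here, 6 kept their call with each library left out.

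**Figure D4:**
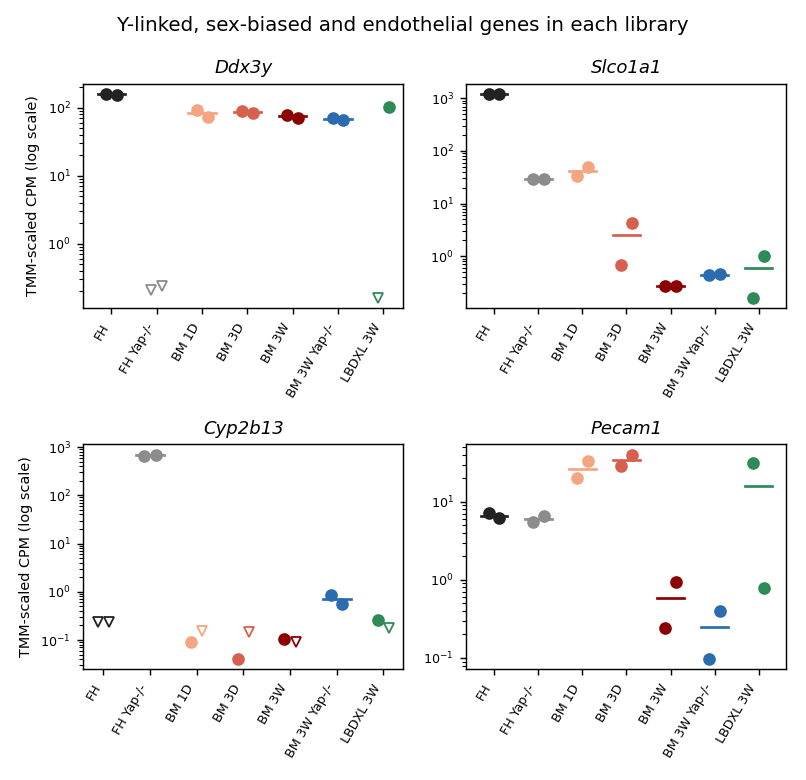
TMM-scaled CPM on a log axis (y) of a Y-linked gene (Ddx3y), a male-biased gene (Slco1a1), a female-biased gene (Cyp2b13) and an endothelial gene (Pecam1) in each library by group (x). Filled points are measured values, bars are means where both libraries hold counts, and open triangles are libraries at 0 counts, drawn at the level of 3 counts. Ddx3y has 0 counts in both FH Yap-/- libraries and in LBDXL 3W 1.

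BM 3W Yap-/- cells were compared with BM 3W. Hepatocyte genes were higher and matrix, YAP target and macrophage genes lower. Cyp3a11 stood at 5409.9 ± 887 against 21.0 ± 13.4 CPM, log2 8.01 ± 1.20, Cps1 at 2913 ± 314 against 40.8 ± 44.8 CPM, log2 6.16 ± 0.96 and Hnf4a at 665 ± 107 against 168 ± 46.4 CPM, log2 1.98 ± 0.32. Cyp2b10 stood at 2472 ± 119.6 against 0.736 ± 0.653 CPM, log2 11.68 ± 1.05 and Cyp2f2 at 756 ± 46.7 against 0.695 ± 0.499 CPM, log2 10.06 ± 0.96. Col1a1 was at 42.0 ± 1.51 against 3128 ± 1466 CPM, log2 -6.22 ± 0.76, Spp1 at 71.3 ± 5.43 against 4687 ± 495 CPM, log2 -6.04 ± 0.77 and Mmp12, a macrophage metalloelastase, at 0.425 ± 0.395 against 726 ± 445 CPM, log2 -10.73 ± 1.13. Ctgf was at 142 ± 12.3 against 810.3 ± 129 CPM, log2 -2.51 ± 0.60, a call lost without BM 3W Yap-/- 1 (adjusted p = 0.0663) or BM 3W Yap-/- 2 (0.0700). Alb stood at 85675 ± 10606 against 16014 ± 18617 CPM and did not pass (adjusted p = 0.119), but did with DESeq2 (0.00778), on log2(FPKM + 1) (0.0387) and without BM 3W 1 (0.00713). Nor did Afp pass, at 252 ± 6.63 against 526 ± 377 CPM (adjusted p = 0.3).

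For 20 genes of the urea cycle and amino acid catabolism, 19 rose, 1 fell and 0 did not pass (19 and 1 over the list alone). Their median was 4.18 (adjusted p = 2.05e-10, and adjusted p = 0.274 with an estimated correlation). Ass1 was at log2 5.16 ± 0.60, Uroc1 at log2 5.67 ± 0.70 and Hgd, of tyrosine breakdown, at log2 3.96 ± 0.59. Of 22 plasma protein genes, 19 rose, 0 fell and 3 did not pass (21 and 0 over the list alone, camera adjusted p = 9.44e-09, and adjusted p = 0.274 with an estimated correlation). Hpx, haemopexin, was at log2 3.04 ± 0.47 and Ambp at log2 2.40 ± 0.38. Of 25 phase I genes, 18 rose, 1 fell and 6 did not pass (19 and 1 over the list alone, camera adjusted p = 9.44e-09, and adjusted p = 0.274 with an estimated correlation). Por was at log2 3.05 ± 0.28. Of 20 phase II conjugation genes, 17 rose, 0 fell and 3 did not pass (17 and 0 over the list alone, camera adjusted p = 1.01e-08, and adjusted p = 0.274 with an estimated correlation). Sult1d1 was at log2 4.15 ± 0.52. Of 19 bile acid genes, 10 rose, 0 fell and 9 did not pass (11 and 0 over the list alone, camera adjusted p = 8.25e-05, and adjusted p = 0.295 with an estimated correlation). Cyp27a1 was at log2 3.11 ± 0.48. Of 15 lipogenesis genes, 5 rose, 0 fell and 10 did not pass (5 and 0 over the list alone, camera adjusted p = 6.86e-04, and adjusted p = 0.274 with an estimated correlation). Mlxipl, the carbohydrate response factor, was at log2 2.73 ± 0.21 and Fasn at log2 2.02 ± 0.37. Of 21 acute phase and inflammatory genes, 11 rose, 2 fell and 8 did not pass (12 and 3 over the list alone, camera adjusted p = 0.00407, and adjusted p = 0.434 with an estimated correlation). Hp, haptoglobin, was at log2 3.28 ± 0.52 and Lbp at log2 3.08 ± 0.39.

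For 21 YAP/TEAD targets, 0 rose, 14 fell and 7 did not pass (0 and 15 over the list alone, camera adjusted p = 4.6e-05, and adjusted p = 0.274 with an estimated correlation). Axl was at log2 -2.84 ± 0.39 and Ccdc80 at log2 -6.17 ± 0.92. Of 28 extracellular matrix and mesenchymal genes, 0 rose, 22 fell and 6 did not pass (0 and 25 over the list alone, camera adjusted p = 2.05e-10, and adjusted p = 0.274 with an estimated correlation). Col1a2 was at log2 -6.46 ± 0.70 and Col3a1 at log2 -6.92 ± 0.82. Of 25 actin cytoskeleton genes, 0 rose, 11 fell and 14 did not pass (0 and 11 over the list alone, camera adjusted p = 1.97e-04, and adjusted p = 0.389 with an estimated correlation). Tagln was at log2 -2.68 ± 0.26 and Actn1 at log2 -2.23 ± 0.28. Of 15 pericentral Wnt targets, 3 rose, 10 fell and 2 did not pass (3 and 10 over the list alone, camera adjusted p = 0.00839, and adjusted p = 0.274 with an estimated correlation). Nkd1 was at log2 -3.03 ± 0.43, and the list did not pass under total count scaling (adjusted p = 0.0661).

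Other-cell markers were lower too, so cell mixture was not separated. Of 12 Kupffer cell and macrophage markers, 1 rose, 9 fell and 2 did not pass (1 and 9 over the list alone, camera adjusted p = 9.21e-04, and adjusted p = 0.274 with an estimated correlation). Csf1r was at 14.7 ± 2.03 against 206 ± 46.1 CPM, log2 -3.82 ± 0.30 and C1qa at log2 -3.18 ± 0.33. Of 14 stellate cell and fibroblast markers, 0 rose, 13 fell and 1 did not pass (0 and 13 over the list alone, camera adjusted p = 5.81e-06, and adjusted p = 0.274 with an estimated correlation). Lum was at log2 -4.38 ± 0.49 and Pdgfrb at log2 -3.46 ± 0.42.

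In BM 3W Yap-/- against BM 3W 2117 genes rose and 2342 fell, and by total counts alone 798 were higher and 5051 lower, with a median shift of -0.64. The count was 2639 without BM 3W 1, 2383 without BM 3W 2 and 1938 without BM 3W Yap-/- 2. Of the genes that rose in BM 3D, 785 (24.7%) were lower in BM 3W Yap-/- than in BM 3W and 218 higher, and of those that fell, 957 (37.8%) were higher and 200 lower.

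Whether Yap-/- differences varied with culture was tested as an interaction, the log2 fold change in culture minus that in fresh cells. The difference was larger in culture for Yap1 itself (-1.71 ± 0.27, adjusted p = 0.00314). It was 7.02 ± 1.20 for Cps1, 5.94 ± 0.77 for Ass1, 8.58 ± 1.14 for Cyp2b10 and 3.02 ± 0.37 for Por. It was -8.13 ± 1.06 for Col1a1, -3.37 ± 0.54 for Axl, -5.74 ± 0.94 for Spp1 and -4.28 ± 0.41 for Csf1r. Cdkn1a, higher in FH Yap-/-, had an interaction of -4.12 ± 0.60, and Slco1a1, a male-biased gene lower there, 6.05 ± 1.18. Y-linked transcripts differed in fresh groups only and other-cell markers in culture, so genotype, sex and cell mixture were not separated. Of 9 male-biased genes, 8 passed above 0 (list median 10.23, adjusted p = 3.87e-09, and adjusted p = 0.176 with an estimated correlation). Of 12 female-biased genes, 4 passed below 0 and 8 did not pass (list median -6.73, adjusted p = 6.26e-07, and adjusted p = 0.176 with an estimated correlation). All 4 Y-linked genes passed above 0 (adjusted p = 0.00802, and adjusted p = 0.322 with an estimated correlation). The interaction passed above 0 in 1133 genes and below 0 in 1248, and by total counts alone in 463 and 2777. A fit on these 8 libraries alone called 4552. The count was 990 without FH 1, 840 without FH 2, 875 and 800 without FH Yap-/- 1 or 2, 1323 without BM 3W 2 and 1120 without BM 3W Yap-/- 2.

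The LBDXL and Yap-/- differences from BM 3W were set against each other across 14100 genes, which are not independent replicates. Col1a1 was lower in both (log2 -8.27 ± 0.84 and log2 -6.22 ± 0.76), and Cyp2b10 higher in both (log2 12.20 ± 1.07 and log2 11.68 ± 1.05). Pearson's r was 0.816 and Spearman's rho 0.818. Both differences share the BM 3W libraries. Unchanged groups simulated against those libraries gave r = 0.472 ± 0.0136 (SD over 50 draws). The covariance was 3.88 against a simulated 0.194 ± 0.00777, a difference of 3.68. Of the calls, 1724 genes were higher in both and 1947 lower in both, while 15 moved opposite ways. With a BM 3W library of its own for each comparison, chosen after the values were seen, r was 0.772 (LBDXL 3W against BM 3W 1, BM 3W Yap-/- against BM 3W 2) and 0.727 (the other way round). The covariance was then 3.86 and 3.68. Called higher in both were 1000 and 745 genes, where independent lists would share 175 and 159, and lower in both 1105 and 1062, against 223 and 249.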

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

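The tests of the first 2 patterns below were chosen only after the results were seen, and those of the last were written before, except its spread over pairs of libraries. A difference between groups singled out the interaction of Yap-/- with culture, where the Yap-/- difference was called higher in culture than in fresh cells in 1133 genes and lower in 1248, and 25 gene lists were called, 0 of them with an estimated correlation (lowest adjusted p = 0.176). Yap1 itself had an interaction of -1.71 ± 0.27 on the log2 scale. Among the genes named for the Yap-/- comparisons, the log2 interaction was above 0 for Ambp 2.23 ± 0.52, Ass1 5.94 ± 0.77, Cps1 7.02 ± 1.20, Cyp27a1 3.85 ± 0.64, Cyp2b10 8.58 ± 1.14, Cyp2f2 11.10 ± 1.11, Cyp3a11 5.44 ± 1.33 and Hgd 4.52 ± 0.77. It was also above 0 for Hnf4a 2.09 ± 0.44, Hp 3.39 ± 0.70, Hpx 3.17 ± 0.63, Lbp 3.23 ± 0.52, Mlxipl 2.48 ± 0.28, Por 3.02 ± 0.37, Slco1a1 6.05 ± 1.18, Sult1d1 4.73 ± 0.68 and Uroc1 5.54 ± 0.87. Genes below 0 were Actn1 -2.52 ± 0.38, Axl -3.37 ± 0.54, C1qa -3.79 ± 0.45, Ccdc80 -6.43 ± 1.21, Cdkn1a -4.12 ± 0.60, Col1a1 -8.13 ± 1.06, Col1a2 -6.29 ± 0.88 and Col3a1 -6.63 ± 0.99. Further genes below 0 were Csf1r -4.28 ± 0.41, Eda2r -7.68 ± 0.80, Lum -3.69 ± 0.71, Mmp12 -10.39 ± 1.96, Nkd1 -4.10 ± 0.59, Pdgfrb -2.72 ± 0.65, Spp1 -5.74 ± 0.94 and Tagln -3.46 ± 0.41. Ddx3y (14.50) and Cyp2b13 (-12.99) had 0 counts in a group, so their size is not measured.

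The first pattern was the gap in sex-biased liver genes between FH Yap-/- and FH. All 4 Y-linked genes lay at or under 3 counts in both FH Yap-/- libraries and over it in both FH libraries, which fits mice of different sex. Loss of Yap1 as the cause of the low Y-linked genes was excluded by their median log2 fold change of 0.032 in BM 3W Yap-/- against BM 3W, and a swap of libraries by Yap1 at -1.90 ± 0.19. Whether sex also lay behind the 115 calls outside the sex-biased and sex chromosome lists cannot be told, because each FH Yap-/- library differed from FH in both. The same holds for the lipid synthesis and p53 target genes called and for the part of the interaction that rests on the fresh libraries.

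The next pattern was high markers of other cells beside low hepatocyte genes in BM 3W. Dilution of hepatocyte RNA as the whole cause was excluded by an interquartile range of 3.77 in the log2 fold changes of 141 hepatocyte genes. A gain of every other cell type alike was excluded by medians of -2.55 for endothelial and 4.05 for Kupffer markers. Stellate marker medians were 0.19 in BM 3D (2 of 14 rose) and -1.22 in BM 1D (0 rose). With actin at 3.05 and 2.86, this argues against stellate cells as its whole source. Whether the 23 matrix and mesenchymal genes higher in BM 3W were made by hepatocytes, the biological explanation, or by other cells cannot be told from mixed libraries. This also limits the differences from BM 3W.

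The last pattern was the excess of higher genes in culture under total count scaling, with a median shift of 1.29 in BM 3W against FH. The 20 most abundant genes as its whole cause were excluded by a shift of 1.10 without them (1.08 to 1.13 over the 4 pairs of a BM 3W and an FH library). The 200 most abundant as the whole cause were excluded by 0.64 (0.613 to 0.670), just over the limit of 0.6 set for it. Without the 1000 most abundant the shift was 0.40, so abundant genes carried part of it, and the source of the remainder stays open. The 200 held 51.6% of FH counts and 23.9% of BM 3W counts. No biological explanation was tested, and RNA content per cell was not measured here.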

How the results depend on the processing

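No test in this part was chosen after its result was seen except the joint removal of LBDXL 3W 1 and BM 3W 2 and the separate BM 3W controls. The genes were, however. Of the results below, 189 are single named genes, preferred for holding under the alternatives. That choice raised the number of values that stayed the same. Over 424 results, 8637 values under an alternative kept their direction and side of the threshold, 355 were weaker, 17 stronger, 79 moved and 12 reversed. A lone library left in a group is assumed to vary like the other groups. Where no cause is named, the cause was not tested.

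Leaving out each library in turn gave counts of called genes of 3842 to 6516 for BM 1D against FH, 3435 to 6056 for BM 3D against FH, 5932 to 8613 for BM 3W against FH, 178 to 1210 for BM 3D against BM 1D, 1664 to 4067 for BM 3W against BM 3D and 1178 to 3171 for LBDXL 3W against FH. For LBDXL 3W against BM 3W the range was 3993 to 6549, for FH Yap-/- against FH 13 to 231, for BM 3W Yap-/- against BM 3W 1938 to 5165 and for the interaction 800 to 3029. Fewer libraries leave fewer degrees of freedom.

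Fits on the compared groups alone gave 0 calls in BM 3D against BM 1D, 1754 in LBDXL 3W against FH, 3997 in LBDXL 3W against BM 3W, 4251 in FH Yap-/- against FH, 4552 in the interaction (2318 above and 2234 below 0) and r = 0.84. These fits estimate the spread from 4 or 8 libraries and hold no replicate block. The DESeq2 Wald test gave 1750 calls in BM 3D against BM 1D (1133 higher, 617 lower) and 374 in FH Yap-/- against FH. Total count scaling gave 8613 in BM 3D against FH. On log2(FPKM + 1) the interaction gave 4244 calls (535 above and 3709 below 0) and r = 0.88, and on log2(FPKM + 0.1) 4061 (527 and 3534) and r = 0.87. Without a filter r was 0.77. With LBDXL 3W 1 and BM 3W 2 both left out, calls were 1186 in BM 3D against BM 1D (834 higher, 352 lower), 1830 in LBDXL 3W against FH (906 and 924) and 234 in FH Yap-/- against FH (130 and 104), and r was 0.79. A separate BM 3W control for each comparison gave r = 0.77 and 0.73.

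Over single libraries left out, r ran from 0.76 to 0.83, Yap1 from -2.0 to -1.81 in FH Yap-/- and from -3.72 to -3.48 in BM 3W Yap-/-, and the share of genes moved the opposite way from 87.5 to 92.5% in LBDXL 3W and from 76.2 to 85.4% in BM 3W Yap-/-. In these versions the lists called numbered 17 to 20 in BM 1D against FH, 21 to 23 in BM 3D against FH, 23 to 24 in BM 3W against FH, 7 to 15 in BM 3D against BM 1D, 21 to 25 in BM 3W against BM 3D, 19 to 24 in LBDXL 3W against FH, 24 to 29 in LBDXL 3W against BM 3W, 12 to 13 in FH Yap-/- against FH, 23 to 27 in BM 3W Yap-/- against BM 3W and 23 to 25 in the interaction.

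With an estimated correlation, camera called 1 list in BM 3D against FH, 2 in LBDXL 3W against FH, 2 in FH Yap-/- against FH and 0 in each of the other 7 comparisons. Directional fry called 2 lists in BM 3D against BM 1D and 7 in FH Yap-/- against FH, and mixed fry 32 in BM 1D against FH, 24 in BM 3D against BM 1D and 32 in LBDXL 3W against FH. With both libraries left out 14 lists were called in BM 3D against BM 1D. Sinusoidal endothelial markers in LBDXL 3W against FH turned upward without LBDXL 3W replicate 2 (adjusted p = 0.634, and 3.54e-09 downward without replicate 1), the library with few endothelial transcripts left out.

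The other reversals were of genes that did not pass in the fit of all groups. Alb in LBDXL 3W against FH was at log2 -0.23 without LBDXL 3W replicate 1 (0.3 at most over single libraries left out) and with both libraries left out, and Hnf4a there at 0.32 under total count scaling and 0.38 on either FPKM scale. Yap1 in LBDXL 3W against BM 3W was at -0.01 with DESeq2 size factors or the DESeq2 test, -0.69 under total count scaling (adjusted p = 0.0247) and on log2(FPKM + 0.1) (0.0209), and -0.66 on log2(FPKM + 1) (0.0178). It thus passed downward in these. Yap1 in LBDXL 3W against FH was at -0.01 without FH replicate 1 and at most 0.16 over single libraries left out.

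Deviations of libraries with the same number from their group means correlated across pairs of groups between -0.02 and 0.46, with a median of 0.02, and 5 of 21 pairs lay over 0.1. A block on the number changed no count of calls by over 1.5 times and ended 4 of 210 list calls. In the 1 simulation, of LBDXL 3W against FH alone, 8% of genes changed 2-fold were called.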

Other observations

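The observations in this part were picked out after the results were seen, though the counts of calls come from fits fixed beforehand. LBDXL 3W 1 lacked Y-linked transcripts, with 0 counts of all 4 genes, while LBDXL 3W 2 held 1704 counts of Ddx3y. The labels give the sex of no library.

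The BM 3W libraries differed in Alb, at 4.35 and 0.482% of their counts. Replicates of FH had a chi-square of 5.53 per degree of freedom and those of LBDXL 3W 237, so fresh libraries resembled each other far more than cultured ones. A spread pooled over all 7 groups may then overstate the noise of fresh libraries (133 calls against 4251 in a fit on those alone) and understate that of cultured ones (742 calls in BM 3D against BM 1D, and 0 in a fit on those alone). This explanation was not tested.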
